A study of Homo sapiens with 12 samples.

How the data were processed

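Poly(A) mRNA was sequenced from total RNA of LNCaP cells in 12 libraries, 3 biological replicates in each of 4 groups, per the labels' protocols and the series design. All libraries carry batch label 1, so no batch could be tested. The authors deposited raw read counts per gene symbol in 2 tables, 1 for each knockdown with its control, and a table of FPKM values for all 12 libraries. The genome build was GRCh38 (hg38), per the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. Each table has 62710 lines for 60835 symbols. A value is given per symbol and repeated on each line that shares it (453 symbols on 2328 lines), so each symbol was kept once. Symbols without an Ensembl identifier (4654) stayed in and held between 0.139% and 0.177% of the counts. The deposited FPKM values were tested against the counts: for all 33045 genes that could be checked, FPKM equalled the count divided by 1 length per gene and the library total, within a relative tolerance of 0.001. Of 56181 identifiers, 56063 were found in GENCODE release 29, 69.4% with the same coordinates and 99.9% overlapping, and that annotation supplied transcript length, GC content and untranslated regions. No value column was left without a sample. The genotype labels of some replicates name neighbouring gene numbers in place of FOXA1 and TRIM28, so they were not used: control groups were taken from the titles and knockdown groups from the treatment labels.

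Library totals ranged from 12256092 to 15152890 counts. Depth was similar across groups, and genes under about 10 counts per library were not tested. A gene passed if 3 libraries reached that level, so a gene low in the controls could enter only by being high in the knockdown. That number followed the smaller group, so leaving out a library eased the filter. In the TRIM28 knockdown 14981 genes were tested with all libraries, and 15383 to 15652 without a library. Lists could gain members that way, and a call gained without a library may rest on them. Replicates were compared by a chi-square test of their counts, and no pair agreed within sampling noise.

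Changed genes were found with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr (minimum count 10, minimum total 15), robust quasi-likelihood fits and F-tests, two-sided, on the 6 libraries of each knockdown and its control, with Benjamini-Hochberg adjustment and a threshold of 0.05. The control groups were compared in the same way. The difference between the effects was tested as a contrast over all 12 libraries with 4 group means. Overlap was set against the product of the call rates per direction. The control groups held different libraries, so no shared-control correction was needed. Standard errors are those of the fitted log2 fold changes, and CPM values are scaled by TMM unless a library total is named.

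The 29 gene lists included androgen-repressed genes, luminal lineage, basal epithelial, neuroendocrine and neural, epithelial-mesenchymal transition, interferon-stimulated, antigen presentation, NF-kB inflammatory, S phase, mitosis, p53 target, cholesterol synthesis, fatty acid synthesis, unfolded protein response and ATF4, hypoxia and glycolysis, imprinted, germline and cancer-testis, KRAB repressor complex partner, immediate early and heat shock genes, stromal and leukocyte markers, ZNF series zinc finger genes, clustered protocadherins, endogenous retrovirus loci, mitochondrially encoded, ribosomal protein and replication-dependent histone genes. They, the tests, the alternatives and the rule for naming genes were set before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over lists with at least 3 tested members. With an estimated correlation no list was called in either knockdown. Fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, called 19 lists in the FOXA1 knockdown, 12 in the TRIM28 knockdown and 0 between the controls. KEGG pathways with at least 10 tested members were tested in the same way, a choice made after the data had been seen.

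Some genes, and 2 of the lists, are not reported here. Named genes included FOXA1, TRIM28, KLK3 and TRIM24, then for each knockdown the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group, a symbol that is not a clone name and no overlap between the libraries of the groups, and up to 4 members with the smallest p of each list. For the overlap these were up to 4 genes per class ranked by the smaller change, and for the difference and the controls the 3 smallest p in each direction. Genes shown for replicate 3 of the TRIM28 knockdown were chosen after its values had been seen.

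The fits were tested on simulated counts with 200 genes changed. At a fold of 2, 76.1% of the changed genes were recovered for the FOXA1 knockdown and 64.2% for the TRIM28 knockdown. For the controls 86.6% were recovered, and for the difference 62.7%. Unchanged genes were also called: 18 for FOXA1, 9 for TRIM28, 12 for the controls and 8 for the difference. For FOXA1 these stood beside 43, 51 and 61 genes recovered at folds of 1.5, 2 and 4, a larger share than the threshold of 0.05 allows on average. The real tests called far more than 200 genes (7840 and 3993), so their recovery may differ. Of 50 random lists, 0 were called. The simulated genes were drawn independently, so this cannot show how the list test behaves for genes that vary together. Other splits of the real libraries called a median of 3 lists for FOXA1, 9 for TRIM28 and 4 for the controls at the preset correlation. Alternatives were RLE, upper-quartile or library-size scaling, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1), a single fit of all 12 libraries, a replicate block, each library left out in turn, a log2 fold change of at least 1, and glmTreat against a fold change of 1.2. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.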

Results

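RNA sequencing was used to measure gene expression in LNCaP cells after knockdown of FOXA1 or TRIM28. LNCaP is an androgen-sensitive human prostate cancer line. FOXA1 is a pioneer transcription factor that opens chromatin in luminal prostate cells, and TRIM28 is a corepressor recruited by KRAB zinc finger proteins. The 12 libraries formed 4 groups of 3 biological replicates, per the series design: a control and a knockdown for FOXA1, and a separate control and knockdown for TRIM28. The design text speaks of short hairpin RNAs, and the treatment labels of the knockdown arms say shRNA. The titles of these arms read SH control, and the column names use SI. What SI stands for is not given. Libraries held between 12256092 and 15152890 counts, and between 24650 and 27031 genes had at least 1 count. Mitochondrial genes took between 3.51% and 4.85% of the counts. Levels are given as CPM, that is counts scaled to library size, mean ± SD with n = 3 per group, and log2 fold changes compare knockdown with control. Whether counting used strand was not given in the sources used here, so genes that overlap an antisense partner, and members of families with near-identical copies such as histones, HLA, ribosomal protein and zinc finger genes, carry extra uncertainty.

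FOXA1 (ENSG00000129514, GRCh38 chromosome 14, 37589552 to 37596059, minus strand) was lower in each of the 3 libraries of its knockdown, at 29.2%, 28.6% and 29.2% of the mean of the controls. The level went from 570 ± 33 CPM to 166 ± 2.1 CPM (log2 fold change -1.78, SE 0.05, adjusted p = 3.15e-22 by edgeR's quasi-likelihood test). TRIM28 (ENSG00000130726, GRCh38 chromosome 19, 58544064 to 58550722, plus strand) stood at 32.0%, 28.5% and 13.99% of control in the 3 libraries of the TRIM28 knockdown. Its mean went from 404 ± 8.8 CPM to 100 ± 39 CPM (log2 fold change -2.01, SE 0.28, adjusted p = 0.00305). FOXA1 was also lower in the TRIM28 knockdown, at 47.3%, 43.0% and 70.1% of control (log2 fold change -0.90, SE 0.17, adjusted p = 0.0055). TRIM28 was at 87.1%, 89.4% and 86.9% of control in the FOXA1 knockdown (log2 fold change -0.19, SE 0.05, adjusted p = 0.00221). That smaller fall did not pass against a minimum fold change of 1.2 (adjusted p = 0.981) or when all 12 libraries were fitted together (adjusted p = 0.562).

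**Figure D1:**
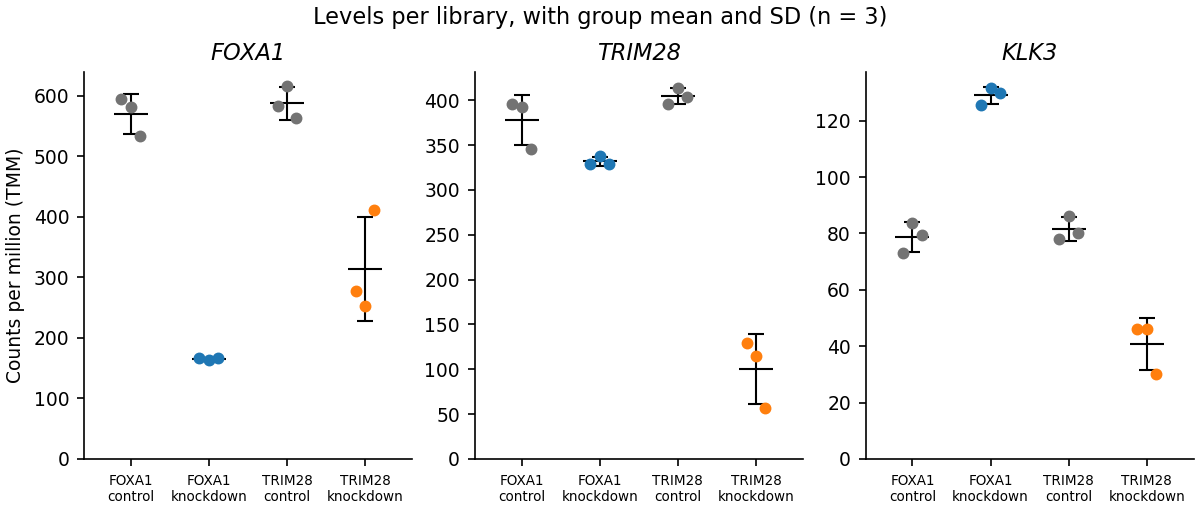
Levels of FOXA1, TRIM28 and KLK3 in CPM after TMM scaling, with 1 point per library for the 4 groups of 3, a bar at each group mean and whiskers of 1 standard deviation. FOXA1 falls to 166 CPM in its own knockdown and TRIM28 to 100 CPM in its own, while FOXA1 is also lower in the TRIM28 knockdown libraries.

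The FOXA1 knockdown asked which genes depend on FOXA1. The largest rise was in CRYAB, which encodes a small heat shock chaperone, from 1.49 ± 0.43 to 55.2 ± 2.6 CPM (log2 fold change 5.22, SE 0.14). HSPB8, which encodes another small heat shock protein, rose by 4.44, and S1PR3, a receptor for sphingosine-1-phosphate, by 4.45 to 55.1 ± 4.7 CPM. PTGES, the inducible prostaglandin E synthase, rose by 5.05 from a level near the detection floor (0.187 ± 0.17 CPM; 5.79 without control replicate 2), AHNAK2 by 5.05 and FAM151A by 4.89. The largest falls were in SLC30A10, a manganese exporter (log2 fold change -3.41), INPP4B, a phosphoinositide phosphatase (-2.91, from 49.7 ± 0.49 to 6.58 ± 0.97 CPM), and WWTR1, which encodes the Hippo pathway coactivator TAZ (-2.91). STYXL2 (-2.86), COL5A2, a fibrillar collagen chain (-2.76), and ALB, which encodes albumin (-2.69), followed. In all, 7840 of 14953 tested genes changed, 3902 of them up and 3938 down, and 1395 changed at least 2-fold. KLK3, which encodes prostate-specific antigen, rose from 78.6 ± 5.3 to 129 ± 3.1 CPM (0.71, adjusted p = 1.90e-11). TRIM24, a transcriptional coregulator, fell by 0.17 (adjusted p = 0.0318), a call lost without control replicate 1 (adjusted p = 0.148), control replicate 2 (0.0901), knockdown replicate 1 (0.14) or knockdown replicate 3 (0.227).

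Androgen-repressed and luminal genes split by direction in the FOXA1 knockdown. Among 17 androgen-repressed genes, 11 fell and 3 rose, also adjusted over the list alone (median -0.84, adjusted p = 0.0624, but called without knockdown replicate 1 at 0.0475). DDC, which encodes aromatic amino acid decarboxylase, changed by -2.32 and HES6 by -1.43, whereas IGFBP3 rose by 4.06 and CCND1, which encodes cyclin D1, by 1.39 to 728 CPM. Luminal lineage genes rose in 12 and fell in 5 of 21 cases, also adjusted over the list alone, with claudin gene CLDN4 (1.35) and E-cadherin gene CDH1 (0.72) among those that rose (adjusted p = 0.691).

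Lists of basal, neuroendocrine and mesenchymal genes were called upward, and those of stromal and leukocyte markers were not called. Of 9 tested basal epithelial genes, 6 rose and none fell (7 and 1 adjusted over the list alone), among them the laminin chain gene LAMB3 (4.10), the keratin genes KRT14 (3.05) and KRT15 (2.78) and the integrin gene ITGB4 (1.64). The list was called upward (adjusted p = 0.00385, but adjusted p = 0.183 with an estimated correlation). Only 6 genes of the list passed the count filter between the controls, and 6 in the TRIM28 pair. Some of the 9 may thus have been tested only because they were high in the FOXA1 knockdown. A rise of such genes follows from the filter and adds no separate evidence. Of 7 neuroendocrine and neural genes, 5 rose and 1 fell, also adjusted over the list alone, with ENO2, a neuronal enolase gene, up by 2.77, NSG1 by 2.21, SYT4 by 1.80 and the chemokine gene CXCL8 by 2.09 (adjusted p = 0.000966, and adjusted p = 0.183 with an estimated correlation). Most of the 29 genes of that list were not tested, and SYP, which encodes the neuroendocrine marker synaptophysin, had -0.02 (adjusted p = 0.960). Epithelial-mesenchymal transition genes rose in 9 and fell in 1 of 18 cases (9 and 2 adjusted over the list alone), including FN1 (fibronectin, 1.33), SNAI2 (2.06), TNC (2.73) and ITGA5 (0.99), with adjusted p = 0.00553 and, with an estimated correlation, adjusted p = 0.299. Stromal markers were not called as a list: of 11, VIM (0.64) and ACTA2 (1.10) rose and PDGFRB had -0.91 at adjusted p = 0.04999, a call lost without control replicate 1 (adjusted p = 0.336) and without each knockdown replicate (0.165, 0.0536 and 0.123). Adjusted over the list alone, 2 rose and none fell (list adjusted p = 0.868). Of 4 leukocyte markers, CORO1A rose (1.02, lost without knockdown replicate 3 at adjusted p = 0.0678) and LCP1 fell (-0.71), with 1 and 1 adjusted over the list alone (list adjusted p = 0.648).

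Cell cycle genes and genes of protein synthesis differed by class. Of 32 S phase genes, 10 rose and 13 fell (11 and 13 adjusted over the list alone), with ribonucleotide reductase gene RRM2 (0.87) and the flap endonuclease gene FEN1 (0.91) up and the helicase gene MCM7 down (-0.48), and the list was not called (adjusted p = 0.868). Mitosis genes fell in 20 and rose in 3 of 32 cases, also adjusted over the list alone, with small changes such as ECT2 (-0.48), ANLN (-0.49) and CENPE (-0.48). The list was called downward (median -0.20, adjusted p = 0.00264, and adjusted p = 0.309 with an estimated correlation). With all 12 libraries in one fit, ANLN (adjusted p = 0.09) and CENPE (0.146) were not called. Among 28 p53 targets, 12 rose and 4 fell, also adjusted over the list alone. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose from 67.7 to 223 CPM (1.72), and TP53INP1, ZMAT3 and PHLDA3 rose by 0.80 to 0.87 (list adjusted p = 0.0574, but called without control replicate 2 at 0.0497 or knockdown replicate 1 at 0.043 or 3 at 0.044). Replication-dependent histone genes rose in 11 and fell in 3 of 28 cases, also adjusted over the list alone, led by H4C8 (2.26, from 34.9 to 168 CPM), H2AC6 (1.46) and H2BC4 (1.41). That list was called upward (adjusted p = 0.00580, and adjusted p = 0.183 with an estimated correlation), and most of its 92 members were not tested. It was formed from symbol prefixes, so it may hold histone genes of other classes. The libraries were made from poly(A) mRNA, so the values cover only polyadenylated histone transcripts. Cytosolic ribosomal protein genes fell together: 56 of 79 fell and none rose (59 and none adjusted over the list alone), with a median of -0.43 and with RPS2 down by 0.58 from 2604 to 1745 CPM and RPL10A by 0.56. The call was strong with the preset correlation (adjusted p = 2.53e-10) and absent with an estimated one (adjusted p = 0.538 with an estimated correlation).

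Of the stress and metabolic lists, those of the unfolded protein response and of hypoxia were called. Genes of the unfolded protein response and of ATF4 fell in 19 and rose in 2 of 29 cases, also adjusted over the list alone. ATF4 itself fell by 0.79 from 658 to 382 CPM, and TRIB3 (-0.94), the cystine transporter gene SLC7A11 (-0.79) and XBP1 (-0.72) fell with it (adjusted p = 6.39e-06, and adjusted p = 0.183 with an estimated correlation). Hypoxia and glycolysis genes rose in 16 and fell in 4 of 27 cases, also adjusted over the list alone, including BNIP3L (1.05), EGLN3 (1.29) and ALDOC (0.81), with adjusted p = 0.000334 and adjusted p = 0.497 with an estimated correlation. Fatty acid synthesis genes rose in 11 and fell in 4 of 22 cases (12 and 5 adjusted over the list alone). The desaturase gene FADS2 rose from 345 to 973 CPM (1.49) and FADS1 by 0.94, while the elongase gene ELOVL7 changed by -1.05 (list adjusted p = 0.0558, but called without control replicate 1 at 0.0389 or 2 at 0.0324, or knockdown replicate 1 at 0.043 or 3 at 0.0312). Of 25 cholesterol synthesis genes, 11 rose and 4 fell (11 and 5 adjusted over the list alone), with the regulator SREBF2 at -0.50 (adjusted p = 0.372). Immediate early and heat shock genes rose in 11 and fell in 5 of 20 cases (12 and 5 adjusted over the list alone), with BAG3, a cochaperone gene, up by 0.97 and MYC (-0.98), JUN (-0.83) and FOS (-1.80) down (list adjusted p = 0.648). With all 12 libraries in one fit, FOS (adjusted p = 0.0809) and JUN (0.137) were not called.

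Immune lists were not called against other genes. By fry, which makes no such comparison, antigen presentation genes (adjusted p = 0.000272) and NF-kB inflammatory genes (5.85e-05) were called upward. Between the controls 13 and 14 genes of these lists passed the count filter, against 15 and 16 here. Some may thus have been tested only because they were high in the FOXA1 knockdown. A rise of such genes adds no separate evidence. Interferon-stimulated genes were not called by fry (0.252). Antigen presentation genes rose in 10 and fell in 1 of 15 cases, also adjusted over the list alone, with CD274, which encodes the checkpoint ligand PD-L1, up by 2.63, NLRC5 by 1.84, ERAP1 by 1.07 and HLA-E by 0.52 (list adjusted p = 0.0695). Interferon-stimulated genes rose in 8 and fell in 8 of 30 cases (9 and 8 adjusted over the list alone), with IRF7 at 0.89 and HERC5 at -1.06. Their median of 0.09 and mean of 0.12 were above 0 while the camera test pointed down (adjusted p = 0.951). NF-kB inflammatory genes rose in 8 and fell in 2 of 16 cases, also adjusted over the list alone, with BIRC3 at 1.46 and the adhesion gene ICAM1 at -0.75 (adjusted p = 0.350).

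Lists tied to TRIM28 function were not called against other genes in the FOXA1 knockdown. By fry, which makes no comparison with other genes, the zinc finger list was called upward (adjusted p = 0.00226) and the germline and cancer-testis list downward (adjusted p = 0.00271). Zinc finger genes of the ZNF series rose in 112 and fell in 68 of 414 cases (106 and 67 adjusted over the list alone, adjusted p = 0.490), with ZNF589 (1.60) and ZNF217 (1.24) among the called genes. Of 24 KRAB repressor complex partners, 4 rose and 6 fell, also adjusted over the list alone, with the histone methyltransferase gene SETDB1 at -0.80 and UHRF1 at 0.79. Their median was 0.03 and their mean -0.01 (adjusted p = 0.900). Of 28 imprinted genes, 6 rose and 8 fell, also adjusted over the list alone, with CDKN1C at 1.95 and PEG3 at -1.42 (median 0.01, mean -0.02, adjusted p = 0.859). Of 16 germline and cancer-testis genes, 4 rose and 6 fell (5 and 6 adjusted over the list alone), with BRDT at -3.88 and TDRD1 at -2.38 (adjusted p = 0.474). None of 3 clustered protocadherins (adjusted p = 0.868) or 6 endogenous retrovirus loci (adjusted p = 0.900) passed the test, adjusted over the list alone included. ERV3-1 had 0.40 (adjusted p = 0.118, or 0.598 with adjusted p = 0.0254 without knockdown replicate 2). ERVMER34-1 was called without knockdown replicate 1 (-0.444, adjusted p = 0.0251). PCDHGC3 had -0.57 (adjusted p = 0.0893). Mitochondrially encoded genes rose in 7 and fell in 1 of 16 cases, also adjusted over the list alone, with MT-ND2 at 0.84 and MT-CO1 at -0.44 (list adjusted p = 0.149, but called without control replicate 3 at 0.0242).

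**Figure D2:**
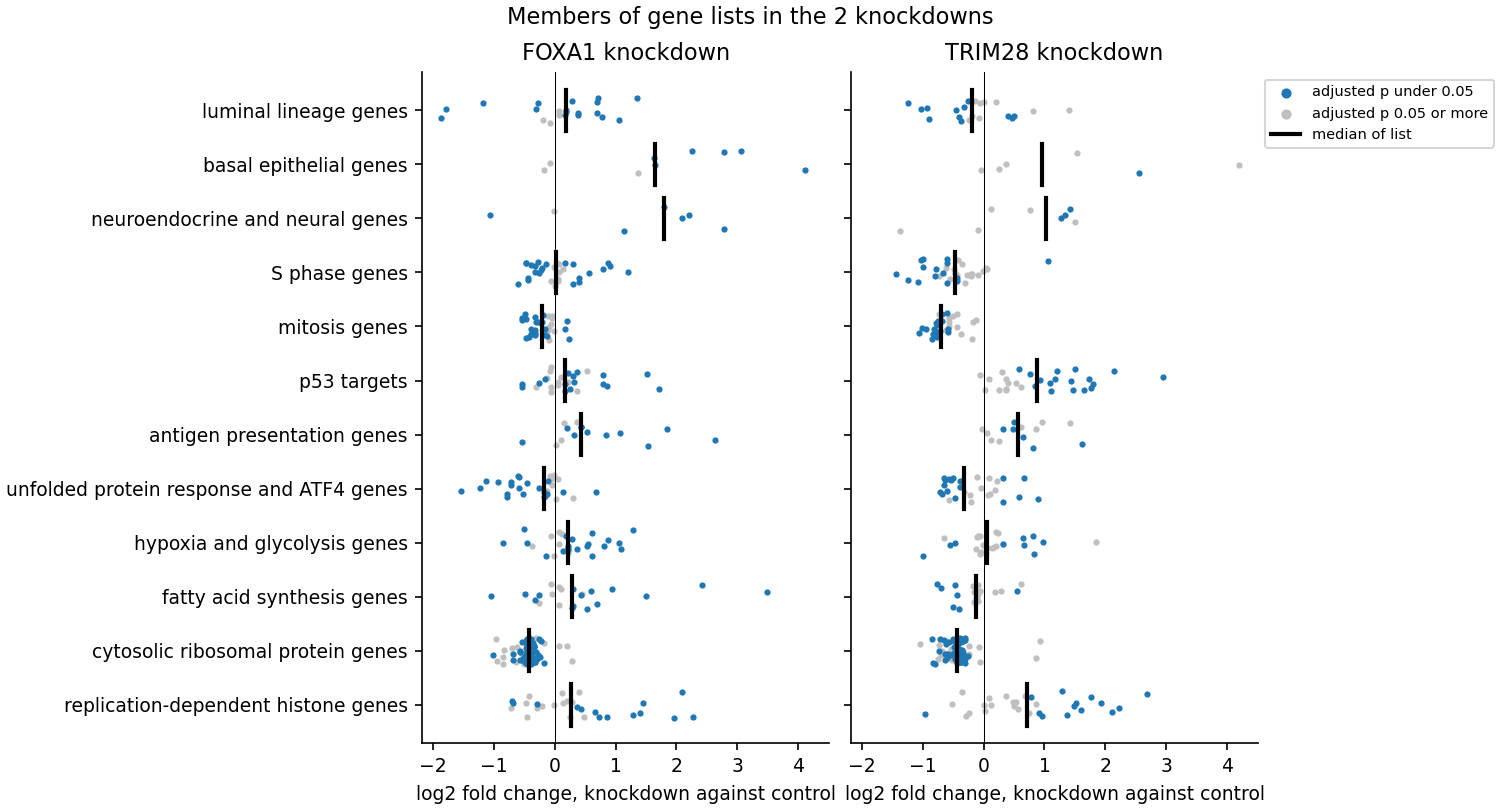
Log2 fold changes of the tested members of 12 gene lists in the FOXA1 knockdown and in the TRIM28 knockdown, with 1 point per gene, blue where the adjusted p was under 0.05, and a black bar at each list's median. Ribosomal protein genes lie below 0 in both panels (medians -0.43 and -0.43), and p53 targets lie higher in the TRIM28 panel (0.89) than in the FOXA1 panel (0.17).

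The TRIM28 knockdown asked which genes depend on TRIM28. The gene with the largest rise was TXNIP, which encodes a thioredoxin-binding regulator of glucose uptake, from 6.39 ± 0.10 to 106 ± 73 CPM (log2 fold change 4.05, SE 0.81, adjusted p = 0.026). IGFBP3, which binds insulin-like growth factors, rose from 2.98 ± 0.78 to 32.9 ± 8.4 CPM (3.47, adjusted p = 0.000112), IGFBP5 by 3.59, the interferon-induced gene IFIT2 by 3.72, the sulfotransferase gene CHST2 by 3.38 and the p53-induced noncoding RNA PINCR by 3.14. Falls were smaller: the islet transcription factor gene RFX6 (-2.04), TRIM28 itself (-2.01), TNS4, which encodes a tensin of epithelial adhesions (-1.93), GCG, which encodes glucagon (-1.93, from 24.4 to 6.41 CPM), the glucose transporter gene SLC2A4 (-1.88) and the RNA-binding protein gene PCBP1 (-1.71). In all, 3993 of 14981 tested genes changed, 1994 up and 1999 down, and 678 changed at least 2-fold. The share of calls that were up was 49.9% with TMM scaling and 63.4% when only library size was used. Some of these calls were lost when 1 control library was left out, with little change in fold: TXNIP (4.03 to 4.05) without control replicate 1 (adjusted p = 0.0597), 2 (0.0782) or 3 (0.0916), IFIT2 (3.39 to 3.94) without control 1 (0.0658), 2 (0.0687) or 3 (0.0619), and IGFBP5 (3.56 to 3.601) without control 1 (0.0536), 2 (0.0658) or 3 (0.0676). CHST2 (3.29 to 3.52) was not called without control 1 (0.0597), 2 (0.068) or 3 (0.0803), and the fall of PCBP1 (-1.56 and -1.66) without control 1 (0.0791) or 2 (0.0726). TXNIP (3.98) was also not called without knockdown replicate 2 (0.0621). The size of the change depended more on other libraries: without knockdown replicate 3 IFIT2 was at 2.39 and IGFBP5 at 2.41, both called. Without control replicate 3 PINCR was at 4.10, and without knockdown replicate 1 PCBP1 was at -2.34, both called.

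Replicate 3 of the TRIM28 knockdown stood apart from replicates 1 and 2. The chi-square statistic per degree of freedom between library counts was 4.62 for replicates 1 and 2 but 29.99 and 27.3 for the pairs with replicate 3, against 3.35 to 7.33 within the other groups. Collagen genes COL3A1 and COL1A2 were at 189 and 86.7 CPM in replicate 3, against 2.26 and 1.79 in replicate 1 and 6.63 and 4.53 in replicate 2. The receptor tyrosine kinase gene MET (101 CPM), the proteoglycan gene VCAN (50.2) and the fetal RNA-binding protein genes LIN28A (21.3) and LIN28B (7.51) were likewise high there, while TXNIP was lower (28.1 CPM against 179 and 120). Without replicate 3, 6966 genes changed (3333 up, 3633 down), and without control replicate 1, 2 or 3 or knockdown replicate 2 the count was 2019, 1817, 2154 or 2488.

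**Figure D3:**
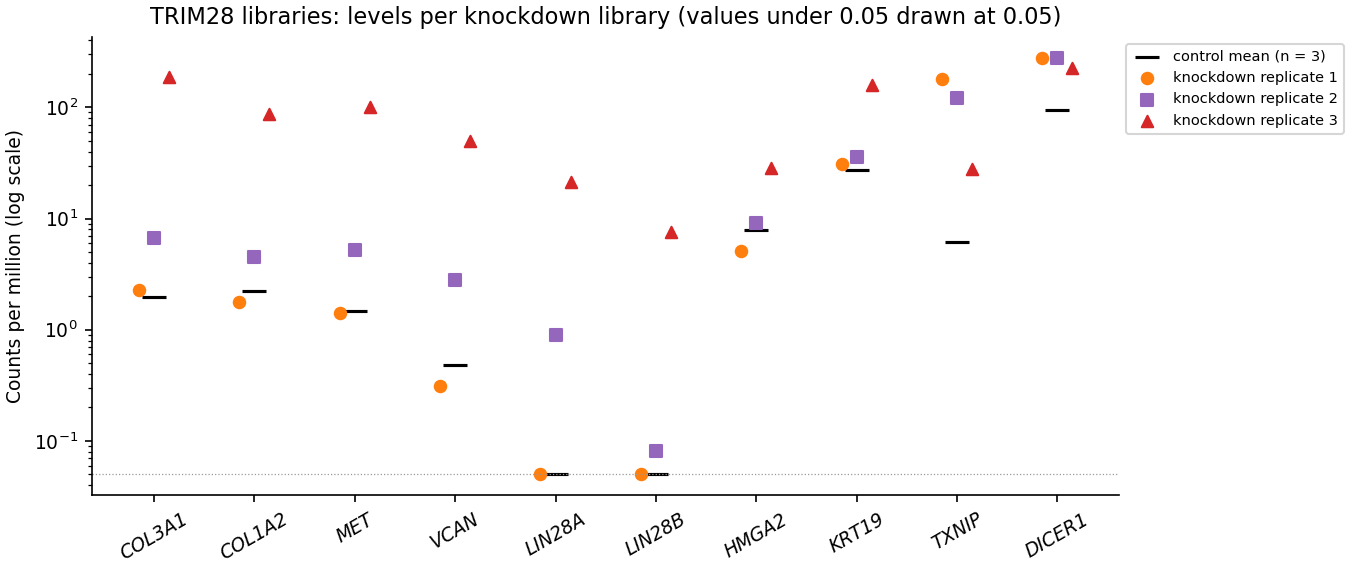
Levels in CPM on a log axis of 10 genes in the mean of the TRIM28 controls and in each replicate of the TRIM28 knockdown, with values under 0.05 CPM drawn at 0.05. COL3A1, COL1A2, MET, VCAN, LIN28A and LIN28B are much higher in replicate 3 than in replicate 2, which is in turn above replicate 1, and TXNIP is lower in replicate 3 (28.1 CPM) than in replicates 1 and 2.

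Several prostate genes fell in the TRIM28 knockdown, namely SLC45A3, a prostate-specific transporter gene, from 303 to 128 CPM (-1.24), the kallikrein genes KLK2 (-1.21) and KLK3 (-1.001, from 81.5 ± 4.2 to 40.7 ± 9.3 CPM), and the protease gene TMPRSS2 (-0.87). These are single genes picked by the naming rule, so they do not show how prostate genes moved as a set. TRIM24 had -0.15 (adjusted p = 0.229, or -0.197 with adjusted p = 0.0274 without knockdown replicate 3). Luminal lineage genes fell in 9 and rose in 3 of 21 cases, also adjusted over the list alone, with the ETS factor gene SPDEF (-1.25, from 266 to 112 CPM) and CLDN3 (-0.93) down and CDH1 up (0.51). Their call (adjusted p = 0.0101) was absent with an estimated correlation (adjusted p = 0.521). Of 17 androgen-repressed genes, 4 rose and 5 fell, also adjusted over the list alone. CCND1 was at 1.11 and HES6 at -1.38, and the list's median of -0.27 and downward test went against its mean of 0.26 (adjusted p = 0.502). Without knockdown replicate 3, 4 luminal genes rose and 11 fell, and 5 androgen-repressed genes rose and 10 fell.

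Proliferation genes fell and p53 targets rose. Mitosis genes fell in 19 of 32 cases and rose in none (21 and none adjusted over the list alone), with the kinase gene AURKB (-1.06), FOXM1, a transcription factor of the mitotic program (-0.85), NUF2 (-1.01) and CCNB1 (-0.77) among them (adjusted p = 1.59e-11, and adjusted p = 0.536 with an estimated correlation). S phase genes fell in 14 and rose in 1 of 32 cases (18 and 1 adjusted over the list alone), including the licensing factor gene CDT1 (-1.44, from 77.1 to 28.4 CPM), E2F1 (-1.24) and MCM2 (-0.99), with adjusted p = 1.60e-08 and, with an estimated correlation, adjusted p = 0.536. Of 28 p53 targets, 17 rose and none fell (22 and none adjusted over the list alone), among them TIGAR, a regulator of glycolysis (1.77, from 3.22 to 11.0 CPM), the kinase gene PLK2 (1.17), AEN (0.93) and SESN2 (0.58), with adjusted p = 2.19e-10 and adjusted p = 0.536 with an estimated correlation. Histone genes rose in 13 and fell in 1 of 30 cases (14 and 1 adjusted over the list alone), led by H2AC6 (1.93) and H2BC5 (1.51), with adjusted p = 5.34e-06 and adjusted p = 0.521 with an estimated correlation. Here too the values cover only polyadenylated histone transcripts, and most of the list was not tested. Between the controls 28 histone genes passed the count filter. Ribosomal protein genes fell in 59 of 78 cases and rose in none (70 and 2 adjusted over the list alone), with a median of -0.43, and with RPS9 at -0.80 and RPL10A at -0.73. The list was called downward (adjusted p = 6.48e-19, and adjusted p = 0.521 with an estimated correlation). Without knockdown replicate 3, 32 mitosis genes fell and none rose, 29 S phase genes fell and 1 rose, and 25 p53 targets rose and none fell. In that setting 17 histone genes rose and 2 fell, and 58 ribosomal protein genes fell and 2 rose. With all libraries of the pair, fry did not call mitosis genes (adjusted p = 0.0658), S phase genes (0.0556) or p53 targets (0.0563). It called histone genes upward (0.0304) and ribosomal protein genes downward (0.0304).

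Zinc finger genes rose after TRIM28 knockdown. Of 411 genes of the ZNF series, 105 rose and 16 fell (112 and 17 adjusted over the list alone), among them ZNF117 (1.69, from 5.71 to 18.4 CPM), ZNF737 (1.17), ZNF605 (1.16) and ZNF264 (0.98, from 46.7 to 92.2 CPM). The list was called upward with a median of 0.23 (adjusted p = 2.71e-05, and adjusted p = 0.234 with an estimated correlation), and 148 rose and 48 fell without knockdown replicate 3. Of 6 endogenous retrovirus loci, 3 rose and none fell (3 and 1 adjusted over the list alone), with ERVE-1 at 1.61 and the list at adjusted p = 0.229. Of 4 clustered protocadherins, PCDHGB6 rose (1.98, lost without control replicate 1 at adjusted p = 0.0737 or 2 at 0.0757), with 2 up adjusted over the list alone. The list was not called by camera (adjusted p = 0.266). It was called upward without control replicate 1 (0.0146), 2 (0.0118) or 3 (0.0251) or knockdown replicate 2 (0.0381). Leaving out a library eased the count filter, so those calls may rest on added members that are high in the knockdown. Between the controls 3 protocadherins passed the filter. Imprinted genes rose in 2 and fell in 2 of 28 cases, also adjusted over the list alone, with IGF2R at 0.55 and PEG3 at -0.88 (adjusted p = 0.606). Of 16 germline and cancer-testis genes, 1 rose and 2 fell, also adjusted over the list alone, with MAGEA12 at 0.49 and PAGE1 at -0.37 (adjusted p = 0.471). Of 24 KRAB repressor complex partners, 1 rose and 4 fell (1 and 3 adjusted over the list alone), with the DNA methyltransferase gene DNMT3A at 0.88 and SUMO2 at -0.50 (adjusted p = 0.482). Without knockdown replicate 3, 3 of 6 retrovirus loci and 3 of 6 protocadherins rose and none fell. In that setting 2 imprinted genes rose and 5 fell, 1 germline gene rose and 4 fell, and 5 repressor complex partners rose and 12 fell. With all libraries of the pair, fry called zinc finger genes (adjusted p = 0.00761), retrovirus loci (0.0348) and protocadherins (0.0277) upward. It called germline genes (0.0304) and repressor complex partners (0.0304) downward and did not call imprinted genes (0.276). Fry makes no comparison with other genes.

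Antigen presentation genes rose in 6 of 14 cases and fell in none (7 and none adjusted over the list alone), with HLA-B (0.65) and HLA-E (0.50) among them. The list was called upward by camera (adjusted p = 0.00285, and adjusted p = 0.234 with an estimated correlation). Between the controls 13 of its genes passed the count filter. Interferon-stimulated genes rose in 4 and fell in 1 of 29 cases (2 and 1 adjusted over the list alone), with PARP14 at 0.74 (list adjusted p = 0.581). NF-kB inflammatory genes rose in 2 and fell in 1 of 16 cases, also adjusted over the list alone, with the cytokine gene LIF at 1.99 and the inhibitor gene NFKBIA at -0.42 (adjusted p = 0.552). Stromal markers rose in 2 of 9 cases (3 adjusted over the list alone), with ACTA2 at 1.41 and COL5A1 at 2.74 with adjusted p = 0.101, or 1.01 with adjusted p = 0.0133 without knockdown replicate 3 (list adjusted p = 0.0286, and adjusted p = 0.536 with an estimated correlation). Epithelial-mesenchymal transition genes rose in 3 of 18 cases (2 adjusted over the list alone), with ITGA5 at 0.75 (list adjusted p = 0.0129, and adjusted p = 0.536 with an estimated correlation). Without knockdown replicate 3 neither list was called (adjusted p = 0.235 and 0.219 in that order), nor was either with a stricter filter on low counts (0.173 and 0.0852). Basal epithelial genes rose in 1 of 6 cases (3 adjusted over the list alone, adjusted p = 0.117, but called upward without control replicate 2 at 0.0392 or knockdown replicate 1 at 0.00153), with the laminin gene LAMB3 at 2.55 (1.89 without knockdown replicate 3). Neuroendocrine and neural genes rose in 3 of 8 cases (3 up and 1 down adjusted over the list alone, adjusted p = 0.0754, but called upward without control replicate 2 at 0.0112 or knockdown replicate 1 at 0.0459), with ENO2 at 1.33. Of 4 leukocyte markers LCP1 fell (-0.57), also adjusted over the list alone, and the list's median of 0.24 and mean of 0.22 went against its downward test (adjusted p = 0.843). Without knockdown replicate 3, 7 antigen presentation genes rose and none fell, 5 interferon-stimulated genes rose and 6 fell, and 2 NF-kB genes rose and 3 fell. In that setting 4 stromal markers rose and none fell, 5 mesenchymal genes rose and 1 fell, 2 basal genes rose and none fell, 4 neuroendocrine genes rose and 1 fell, and 1 leukocyte marker fell and none rose.

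Metabolic and stress lists had mixed members. Unfolded protein response and ATF4 genes fell in 13 and rose in 5 of 29 cases (14 and 6 adjusted over the list alone), with the chaperone genes MANF (-0.69), SDF2L1 (-0.71) and CALR (-0.54) down and the lipoprotein receptor gene VLDLR up (0.89). Their call (adjusted p = 0.0325) was absent with an estimated correlation (adjusted p = 0.672), with a stricter filter (0.103), and without knockdown replicate 1 (0.0919) or 2 (0.117). Fatty acid synthesis genes fell in 6 and rose in 1 of 20 cases (6 and 2 adjusted over the list alone), with ELOVL5 (-0.77, from 796 to 466 CPM), FADS1 (-0.70) and FADS2 (-0.47) down and GPAM up (0.55). That call (adjusted p = 0.0399, and adjusted p = 0.536 with an estimated correlation) was lost when any 1 of the 6 libraries was left out (0.0600 to 0.140) and with a stricter filter (0.0852). Cholesterol synthesis genes rose in 6 and fell in 5 of 25 cases (6 and 7 adjusted over the list alone), with EBP at -1.02. Their median of -0.07 and mean of -0.03 were below 0 while the test pointed up (adjusted p = 0.977). Hypoxia and glycolysis genes rose in 6 and fell in 3 of 27 cases (7 and 3 adjusted over the list alone), with the prolyl hydroxylase gene P4HA2 at 0.98 (adjusted p = 0.0761, but called upward without control replicate 2 at 0.00245 or knockdown replicate 1 at 0.0157 or 2 at 0.0419). Immediate early and heat shock genes rose in 1 and fell in 3 of 21 cases, also adjusted over the list alone, with JUND at -0.84 and the heat shock gene HSPB1 at -0.70 (adjusted p = 0.346, but called downward without knockdown replicate 3 at 0.0486). Of 16 mitochondrially encoded genes, 2 rose and 1 fell, also adjusted over the list alone, with MT-TP at 0.52. Their median of -0.02 and mean of -0.00 were below 0 while the test pointed up (adjusted p = 0.939). Without knockdown replicate 3, 6 unfolded protein response genes rose and 19 fell, 4 fatty acid genes rose and 9 fell, and 7 cholesterol genes rose and 8 fell. In that setting 7 hypoxia genes rose and 8 fell, 3 immediate early genes rose and 9 fell, and 3 mitochondrial genes rose and 1 fell.

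The control groups of the pairs were compared to see how far the libraries differed apart from the knockdowns. HSPA1B, an inducible heat shock gene, had the smallest p among genes higher in the TRIM28 control (log2 difference 0.40, 33.7 against 44.5 CPM, adjusted p = 0.642), followed by PWP2 (0.85) and PLEKHG4 (0.39), both also at adjusted p = 0.642. DENND1C (-0.30, adjusted p = 0.680), the cholesterol synthesis gene CYP51A1 (-0.73, adjusted p = 0.927) and the ribosomal gene RPS14 (-0.21, adjusted p = 0.992) led in the other direction. No gene of 14839 passed edgeR's quasi-likelihood test, while 635 had an unadjusted p under 0.05, and DESeq2 called 0. Lists of mitosis (adjusted p = 0.00823), cholesterol synthesis (0.0152) and ribosomal protein genes (5.96e-05, median -0.06) were called lower in the TRIM28 control and immediate early genes higher (0.0338), without any called member, and adjusted over the list alone 1 cholesterol synthesis gene was lower and 1 immediate early gene higher. With an estimated correlation none was called (adjusted p = 0.740, 0.709, 0.740 and 0.740). Leaving out FOXA1 control replicate 1 gave 1 called gene and leaving out TRIM28 control replicate 2 gave 2. No pair of control libraries agreed within sampling noise, and the chi-square statistic per degree of freedom across the control groups was 2.69 to 6.73.

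The knockdowns were next set side by side, each against its own control libraries. Genes up in both included TXNIP (log2 fold change 4.07 in the FOXA1 and 4.05 in the TRIM28 knockdown), IGFBP3 (4.06 and 3.47), CHST2 (3.75 and 3.38) and IGFBP5 (3.16 and 3.59). Genes down in both included GCG (-2.45 and -1.93), SLC2A4 (-2.21 and -1.88) and INPP4B (-2.91 and -1.56). Of 14498 genes tested in both, 1421 were up in both where independent lists would give 504, and 1461 were down in both where they would give 538. Only 128 changed in opposite directions (1042 for independent lists), so 95.7% of the shared calls, 2882 genes, had the same direction. Opposite changes were found for FRMPD2 (-1.51 and 1.28), the kinase gene PIM1 (1.496 and -0.86), RAB39B (-0.88 and 0.81) and KLK3 (0.71 and -1.001). Across genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.616, a Spearman correlation of 0.604 and a covariance of 0.220, and Fisher's exact test over genes gave an odds ratio of 4.09. Without replicate 3 of the TRIM28 knockdown, 4388 genes shared a direction (92.3% of shared calls), a setting added after the data had been seen.

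**Figure D4:**
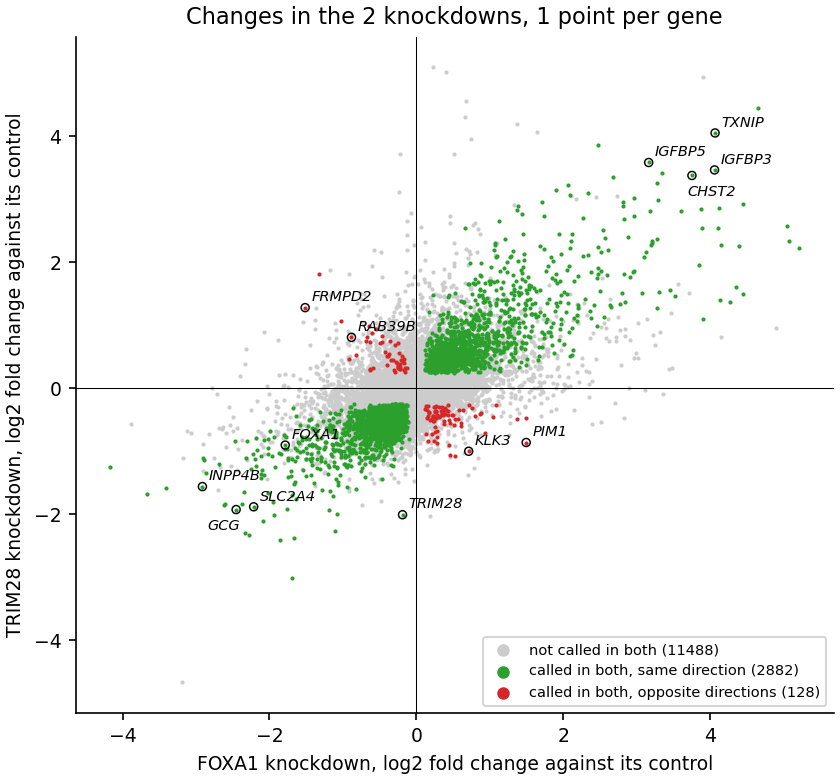
Log2 fold change in the TRIM28 knockdown against that in the FOXA1 knockdown for the 14498 genes tested in both, coloured by whether a gene was called in both with the same direction (2882), in both with opposite directions (128) or not in both, with named genes labelled. Most genes called in both lie in the quadrants of the same sign.

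The difference between the knockdown effects was tested directly with all 12 libraries. FAM111B, a replication-associated protease gene, rose in the FOXA1 knockdown from 161 to 675 CPM (2.07) against 0.02 in the TRIM28 knockdown, a difference of 2.06 on the log2 scale. FADS2 differed by 1.98 and the calpain gene CAPN2 by 2.05 (2.32 and 0.28). UTRN, which encodes utrophin, differed by -1.36 (-1.68 and -0.31), SLC30A4, a zinc transporter gene, by -1.06 (-2.02 and -0.95) and the chloride-proton exchanger gene CLCN3 by -0.995 (-0.43 and 0.57). In all, 1683 of 15921 genes differed, 952 with a higher log2 fold change in the FOXA1 knockdown and 731 with a lower one, and 3528 differed without TRIM28 knockdown replicate 3. Higher and lower are meant with the sign, so a higher log2 fold change can be a smaller fall. FOXA1 itself differed by -0.87 (adjusted p = 0.0144) and TRIM28 by 1.83 (adjusted p = 0.00647). Of the lists, S phase genes (median difference 0.58, adjusted p = 6.81e-11), mitosis genes (0.42, adjusted p = 3.79e-07), fatty acid synthesis genes (0.22, adjusted p = 1.22e-07), luminal lineage genes (0.27, adjusted p = 0.000682) and immediate early genes (0.33, adjusted p = 0.00602) had the higher log2 fold changes in the FOXA1 knockdown. The p53 targets (-0.65, adjusted p = 7.69e-08), androgen-repressed genes (-0.57, adjusted p = 0.00138) and zinc finger genes (-0.11, adjusted p = 0.0122) had the higher log2 fold changes in the TRIM28 knockdown. With an estimated correlation none of these was called, with adjusted p = 0.378, 0.624, 0.0919, 0.256 and 0.378 for the first group and adjusted p = 0.472, 0.256 and 0.335 for the other. Ribosomal protein genes did not differ by the test (median difference -0.00, adjusted p = 0.886). Mitosis genes were lower in both, with medians of -0.20 in the FOXA1 and -0.70 in the TRIM28 knockdown. Androgen-repressed genes had medians of -0.84 and -0.27 in that order.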

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

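Of the tests in this part, those of stromal RNA and of a wrong label in replicate 3, of lower FOXA1 in the TRIM28 knockdown, and of trends and scaling for ribosomal protein genes were chosen only after the result had been seen. The genes listed first are reported ones that changed in opposite directions in the knockdowns with a tested difference between the effects by edgeR over all 12 libraries.

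KLK3 had 0.71 in the FOXA1 and -1.001 in the TRIM28 knockdown, a log2 difference of 1.73 (adjusted p = 7.9e-06). TMPRSS2 had 0.28 and -0.87, a difference of 1.16 (adjusted p = 8.53e-08). The desaturase genes FADS2 (1.49 and -0.47) and FADS1 (0.94 and -0.70) differed by 1.98 (adjusted p = 2.53e-09) and 1.65 (adjusted p = 8.53e-08), and the elongase gene ELOVL5 (0.28 and -0.77) by 1.06 (adjusted p = 4.27e-07). HSPB1 (0.26 and -0.70) differed by 0.97 (adjusted p = 3.71e-05) and PIM1 (1.496 and -0.86) by 2.37 (adjusted p = 6.38e-07). With the opposite sign, FRMPD2 (-1.51 and 1.28) differed by -2.78 (adjusted p = 0.00167), RAB39B (-0.88 and 0.81) by -1.68 (adjusted p = 0.00144) and CLCN3 (-0.43 and 0.57) by -0.995 (adjusted p = 1.9e-06). Each of these genes was called for the difference without TRIM28 knockdown replicate 3 as well, with KLK3 at 1.55 and FADS2 at 2.03.

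Replicate 3 of the TRIM28 knockdown held collagens, MET and LIN28A at levels far above the other libraries. Stromal cells or their RNA would bring all of their abundant transcripts, but 8 such genes had a median gain of -1.13 CPM over replicates 1 and 2 while COL1A2 gained 83.5 CPM, and 10 abundant heart muscle genes gained a median of 0.408 CPM while MYH6 gained 18.5 CPM, so neither accounts for the rise as a set. Single members did rise, with VIM up by 9.89 and S100A6 by 8.13 CPM among the stromal genes and TTN by 19.1, ACTC1 by 3.47 and MYL4 by 1.92 CPM among the heart muscle genes. A wrong label or control cells would bring TRIM28 up, but it stood at 13.99% of control there. Carriers of the let-7 seed match were shifted upward (rank 0.705% among 7-base words in 3' untranslated regions), which a loss of let-7 repression predicts. Matches of other microRNAs ranked higher, and the median shift was small (0.173 with and 0.0534 without the match). Replicates 1 and 2 had similar medians (0.162 and 0.0678, then 0.155 and 0.0596), though let-7 ranked at 33.2% and 19.5% there. Lost let-7 repression may thus be at most a part of the rise. RNA of other cells that lack the tested genes, or of a mix of cells, stays open and was not tested, and so does the lower TRIM28 level of that library as a biological cause.

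Both knockdowns moved genes in the same direction. A shared trend with GC content or gene length was argued against, since the correlation of the effects was 0.620 after length, GC content and level were regressed out and 0.618 before. Without 570 genes of cell cycle, ribosome, splicing, histone and stress lists and pathways the correlation was 0.613, so those genes alone did not carry it. They were few among the 14498 genes tested in both, so leaving them out could hardly lower the correlation. A shared loss of proliferation that also moves unlisted genes therefore stays open. Lower FOXA1 in the TRIM28 knockdown could account for part of the shared direction: 10.8% of the TRIM28 calls (427 of 3943) were uncalled or opposite in the FOXA1 knockdown with a tested difference, which neither excludes nor requires it. The order of the libraries gives no more, with 3 values of FOXA1, and a response of LNCaP cells common to any knockdown also stays open, untested.

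Ribosomal protein genes were lower in both knockdowns. Scaling of the libraries was argued against, since the median nearest to 0 over 4 scalings and both knockdowns was -0.357. A trend with length, GC content and level was argued against in the FOXA1 knockdown (median residual -0.295), but left a residual of -0.0621 in the TRIM28 knockdown, so there it may account for most of the fall. The ribosomal protein genes were part of these fits, so their own shift may have been absorbed. The trend explained 3.58% of the variance of the FOXA1 effects and 13.1% of that of the TRIM28 effects. A lower level of terminal oligopyrimidine mRNAs as a class predicts lower translation factor genes that encode no ribosomal protein, and 19 such genes had medians of -0.378 and -0.417, with 17 and 15 called lower. After the same regression their median residuals were -0.289 in the FOXA1 and -0.313 in the TRIM28 knockdown. Their transcripts were longer, with a median of 3164 bases against 1170 for ribosomal protein genes. That class effect is a candidate explanation, tested on the same data in which the fall was seen.

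Other splits of the same libraries were run for each count. With 3 libraries against 3 there are 10 splits, too few for a share under 0.1. The real split gave 7840 changed genes for FOXA1 (1 split of 10 as large, highest other 0), 3993 for TRIM28 (1, highest other 0), and 0 for the controls (10, highest other 2), and 9 called lists for FOXA1 (1, highest other 6) and 14 for TRIM28 (2, highest other 14). For the difference between effects, 4 of 100 draws gave at least the 1683 genes of the real grouping, and the highest other was 3459. The 3 others all kept the real FOXA1 split, and 88 draws that broke it gave at most 273. Draws that break a split remove that knockdown's effect, so the low counts say little about a difference between effects, and chance is left open there. For the overlap, 1 of 100 draws was as large as 2882, with 0 in the highest other, but a broken split left no called gene in its knockdown, so a shared count of 0 was fixed beforehand and that comparison decides nothing about chance.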

How the results depend on the processing

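Of the settings reported here, the overlap and list members without TRIM28 knockdown replicate 3 were chosen only after the result had been seen. In the FOXA1 knockdown, 7840 changed genes became 1395 with a log2 fold change of at least 1 and 4305 with glmTreat, and leaving out libraries gave 7070 to 7637. In the TRIM28 knockdown, 3993 became 678 with a log2 fold change of at least 1, 1625 with glmTreat, 1224 on log2(FPKM + 1) without a filter, and 1817 (without control replicate 2) to 6966 (without knockdown replicate 3) when a library was left out. The difference between effects went from 1683 to between 1176 and 3528 (without TRIM28 knockdown replicate 3). The controls gave 0 to 2 called genes without 1 library. Shared directions went from 2882 to 327 with a log2 fold change of at least 1 and to 4388 without TRIM28 knockdown replicate 3. A stricter threshold lowers counts by construction, and the cause of the other changes was not tested. Called lists went from 9 and 14 to 0 and 0 with an estimated correlation, and to 9 in the TRIM28 knockdown with a stricter filter. Without 1 library they went to 9 to 12 and 11 to 17. Leaving out a library also eased the count filter, so lists could gain members there.

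The direction of a list's test turned only where no call was made. In the FOXA1 knockdown these included protocadherins (adjusted p from 0.830 to 0.958 without 1 library), interferon-stimulated genes (0.930 to 1.00), luminal genes (0.503 to 0.969), S phase genes (0.634 to 0.969) and stromal markers (0.840 to 1.00). In the TRIM28 knockdown they were cholesterol synthesis genes (0.677 to 0.988), leukocyte markers (0.721 to 0.967), mitochondrial genes (0.363 to 0.988, and 0.989 with the replicate block) and NF-kB genes with a stricter filter (0.868). Among named genes, LYZ ranged from -0.33 to 0.10, PCDHGA10 from -0.12 to 0.32 and PCDHGA8 from -0.58 to 0.27 in the FOXA1 knockdown, and CD8A from -0.10 to 0.49 in the TRIM28 knockdown, none of them called. Over all settings and named genes that are reported, 2236 values for FOXA1 and 2045 for TRIM28 kept their direction and side of the threshold, 35 and 158 lost a call, and 2 and 51 gained one.

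Replicate numbers did not pair the libraries: same-number deviations correlated between -0.0206 and 0.0818 for FOXA1 and between -0.0754 and 0.00692 for TRIM28, and not every library correlated best with its own number. With the replicate block, 7997, 3846 and 1579 genes were called for FOXA1, TRIM28 and the difference, 2873 shared a direction, 0 differed between controls, and 10 and 15 lists were called. The fatty acid list in the FOXA1 knockdown (adjusted p = 0.0358) and the neuroendocrine list in the TRIM28 knockdown (0.0487) were called with the block and not without it. At a fold of 1.5 the simulated tests recovered 64.2% for FOXA1 and 47.8% for TRIM28.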

Other observations

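Of the results in this part, the pathway tests and the choice of genes for replicate 3 were made only after the data had been seen. In the FOXA1 knockdown, pathways of cell adhesion and guidance were called upward beside the lists described before. The KEGG focal adhesion pathway rose in 70 and fell in 26 of 140 genes, with CAPN2, CCND1 and FN1 among those that rose (adjusted p = 0.00017 with camera over 327 pathways). Axon guidance rose in 67 and fell in 25 of 135, with the semaphorin receptor gene NRP1, SEMA3C and UNC5B among the called genes (adjusted p = 0.000462), and Hippo signalling rose in 60 and fell in 21 of 121, with ID1, ID2 and WNT7B (adjusted p = 0.000565). Genes of aminoacyl-tRNA synthesis, which load amino acids onto transfer RNAs, fell in 27 and rose in 2 of 40 cases, with YARS1, IARS1 and AARS1 (adjusted p = 0.00017, and adjusted p = 0.488 with an estimated correlation). The one-carbon pool by folate fell in 8 and rose in 2 of 14, with MTHFD2 (adjusted p = 0.0339). Of the 61 pathways called, 0 were called with an estimated correlation.

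In the TRIM28 knockdown, pathways of mitochondrial respiration, splicing and DNA replication were called downward. Oxidative phosphorylation genes fell in 41 and rose in 7 of 113 cases, with ATP5MC1, NDUFV1 and CYC1 (adjusted p = 2.03e-05), and tricarboxylic acid cycle genes fell in 15 and rose in 1 of 27, with the citrate synthase gene CS, PC and SUCLG1 (adjusted p = 7.49e-05). Spliceosome genes fell in 42 and rose in 4 of 118, with SNRPA and SNRPB (adjusted p = 0.000117), and DNA replication genes fell in 16 of 33 and rose in none (adjusted p = 1.49e-08). TGF-beta signalling genes rose in 31 and fell in 5 of 82, with SMAD3, TGFBR2, ID2 and BMP7 (adjusted p = 0.00174), and genes of receptors for extracellular matrix rose in 14 and fell in 3 of 50, with FRAS1, COL6A2 and RELN (adjusted p = 0.00147). Of the 50 pathways called, 0 were called with an estimated correlation (adjusted p = 0.732 for each of these). The pathways were not tested without knockdown replicate 3, which alone held collagen genes at high levels. Without it the stromal and mesenchymal lists were no longer called by camera (adjusted p = 0.235 and 0.219). Whether the matrix receptor and TGF-beta calls depend on that library is therefore not known.

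Replicate 3 of the TRIM28 knockdown held 137 genes at 5 CPM or more and at least 5 times above every other library of the pair, against 1 such gene in replicate 1 and 0 in replicate 2, and they took 0.222% of its counts. Levels per library total were 21.1 CPM for IGF2BP1, 34.4 for IGF2, 18.8 for H19, 11.2 for the transcription factor gene GATA4 and 19.2 for MYH6. KRT19 stood at 159 CPM against 31.0 and 35.9 in replicates 1 and 2, and DICER1 at 227 against 281 and 276, where the controls averaged 95.4. Replicate 3 also had the most genes with a count (27031) and the lowest mitochondrial share (3.51%) of the 12 libraries. The library effects of replicates 1 and 2 correlated at 0.860 across genes, against 0.524 and 0.579 for the pairs with replicate 3. Their correlations with the mean FOXA1 effect were 0.632, 0.597 and 0.431.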
